A study of Homo sapiens with 12 samples.

How the data were processed

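Cells of the human embryonic stem cell line HUES8 were compared with neural progenitor cells made from them, here called ESC and NPC. Per the labels' protocols, neural induction lasted 7 days with dual SMAD inhibition, in which SB431542 (2.5 uM, an inhibitor of the Nodal and activin receptors) and LDN193189 (0.05 uM, an inhibitor of BMP receptors) were added, and SB431542 was absent for the last 2 days. Both cell states were measured by RNA-seq of total RNA depleted of rRNA and by sequencing of ribosome-bound RNA, with 3 libraries per state and assay and 12 libraries in all. How ribosomes were isolated, and whether a nuclease step left footprints or longer fragments, is not given in the sources used here, so the second assay is called ribosome-bound RNA throughout.

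The values used were the counts per gene as deposited by the authors, whole numbers with no normalization, in a single table of 59050 gene symbols with a column for each library. The submitters' processing notes name cutadapt 1.18, Bowtie 1.2, STAR 2.7.1a and featureCounts 1.6.4, and the builds hg38 and GRCh38. The role of each tool, the annotation release, the counted feature, the use of strand and the treatment of reads with several matches are not given in the sources used here. Values of genes that overlap others, that have an antisense partner (such as EMX2OS beside EMX2) or that share sequence with copies (histone genes, ribosomal protein genes and their pseudogenes, NANOG and NANOGP8, POU5F1 and its pseudogenes) are therefore uncertain. Each column name matched the title of a single sample, and no column was left unused.

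Total counts ranged from 19529738 to 35117370 in the RNA libraries and from 2422756 to 4451196 in the ribosome-bound libraries. A gene with 0 counts in a library could still have been present at up to 3 counts, which was 0.0854 to 0.154 CPM (counts scaled to a common library size) in the RNA libraries and 0.674 to 1.24 CPM in the ribosome-bound libraries. These limits, and the 95% intervals of ratios given for genes with few counts (exact, from the binomial split of the counts), cover counting error only, since reads without molecular identifiers are not independent molecules. Gene types and gene spans came from a RefSeq table of assembly GRCh38.p14, matched by symbol or synonym. Symbols without a match held 1.15% of the RNA counts and 0.87% of the ribosome-bound counts. No genome sequence was used here, so the GC content and coding length of genes were not examined, and gene span was used instead.

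Fold changes of NPC over ESC were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, for each assay in a fit of its own. Translational efficiency, the ratio of ribosome-bound to total RNA per gene, was tested as the interaction of assay and cell state in a single fit over all 12 libraries, on genes that passed the filter in each assay. It is a relative quantity, because each library was scaled to its own total. The level of efficiency within a state was log2 of mean ribosome-bound CPM over mean RNA CPM, each with 0.5 added. The standard error of a log2 fold change was its size divided by the square root of F. That of a list median was taken over the list's members, which are not independent, so it is too small. DESeq2 1.42.0 and limma 3.58.1 served as other tools. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

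A total of 28 gene lists, the genes to be named, the main tests and nearly all alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma), with a preset correlation of 0.01 and again with the correlation between members estimated, and with fry, each with Benjamini-Hochberg adjustment over the lists of a comparison. For each list, members past the threshold were counted with adjustment over all genes and with adjustment over the list alone. The genes named were, per comparison, the 10 largest rises and 10 largest falls past the threshold with every NPC value on one side of every ESC value and a mean of at least 10 CPM in the higher state (for efficiency, at least 5 CPM in each of the 4 groups, with ratios taken between libraries of the same number), leaving out symbols that are bare clone names. POU5F1, NANOG, SOX2, LIN28A, DNMT3B, PAX6, SOX1, NES, OTX2 and LHX2 were added, together with the 2 largest rises and 2 largest falls past the threshold of each list. A fold against a group with 0 counts was computed as a lower bound, against 3 counts over the group.

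The tests were checked on simulated counts with known changes in 50 genes per size of change. At 2-fold, 48% of the changed genes were recovered for RNA, 28% for ribosome-bound RNA and 14% for translational efficiency. At 4-fold the shares were 94%, 96% and 88%. False calls made up 3.94%, 7.44% and 6.36% of the calls. Far fewer genes changed in the simulations than were called in the data, which makes the adjusted limit stricter, so these shares are not those of the real comparisons.

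Groups share replicate numbers in the labels. Whether the numbers pair the libraries was decided from how same-numbered libraries deviated from their group means. In RNA the correlations of these deviations between ESC and NPC were 0.474, 0.322 and 0.661 for numbers 1, 2 and 3. All were above the 0.1 set beforehand, and the numbers were taken to pair these libraries. The main fits, planned without a block, did not include the number. The deviations within a group cancel, so the correlations are not independent of each other. RNA_ESC replicate 1 gave 0.474 and 0.332 with RNA_NPC replicates 1 and 2. RNA_ESC replicate 2 gave 0.481 and 0.322 with them, so numbers 1 and 2 were not told apart. The fit with the number as a block changed no list call for RNA, and the RNA call of HIST1H1T, which it ended, is given with that fit's value. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Alternatives covered scaling, filters on low counts, the replicate block, DESeq2, limma-voom, a minimum fold and the removal of each library in turn. Fits without 2 libraries that stood apart from their group were added after seeing the data.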

Results

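Total RNA and ribosome-bound RNA of HUES8 embryonic stem cells (ESC) and of the neural progenitor cells (NPC) made from them were counted per gene in 3 libraries per state and assay. RNA libraries held 20326398, 26028174 and 19529738 counts in ESC replicates 1, 2 and 3 and 26076504, 35117370 and 32682285 counts in NPC. Ribosome-bound libraries were shallower, with 3069095, 2422756 and 3606539 counts in ESC and 3274208, 3512031 and 4451196 counts in NPC. Protein-coding genes took 94.7% to 95.2% of the counts in every RNA library. In the ribosome-bound libraries their share was 87.9% ± 2.01 (SD, n = 3) in ESC and 82.8% ± 1.62 (SD, n = 3) in NPC. Across genes, which are not independent replicates, the log2 CPM of RNA_ESC replicates 1 and 2 correlated at Pearson r = 0.997, whereas replicate 3 correlated with them at 0.954 and 0.942. RIBO_ESC replicate 2 likewise stood apart, at 0.923 and 0.940 from the other replicates, which correlated with each other at 0.981. NPC replicates correlated at 0.996 to 0.998 in RNA and 0.979 to 0.983 in ribosome-bound RNA.

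The first comparison asked which transcripts changed in abundance during neural induction. RNA of the core pluripotency factors POU5F1 and NANOG fell, while that of the neuroectodermal transcription factors PAX6, SOX1 and OTX2 rose. POU5F1 RNA went from 943 ± 345 CPM in ESC to 21.6 ± 1.62 CPM in NPC (SD, n = 3), 43.7-fold lower, and NANOG from 433 ± 23.1 to 1.24 ± 0.0908 CPM, 349-fold lower. PAX6 rose from 0.709 ± 0.128 to 42.3 ± 1.11 CPM, a 58.9-fold difference, SOX1 from 2.94 ± 0.260 to 46.9 ± 2.63 CPM and OTX2 from 8.70 ± 0.846 to 90.5 ± 3.07 CPM. SOX2, a factor shared by both states, stood at 107 ± 11.9 and 115 ± 6.29 CPM, and the RNA-binding protein LIN28A at 4726 ± 625 and 4475 ± 86.0 CPM, without a detected difference (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.476 and 0.554).

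**Figure D1:**
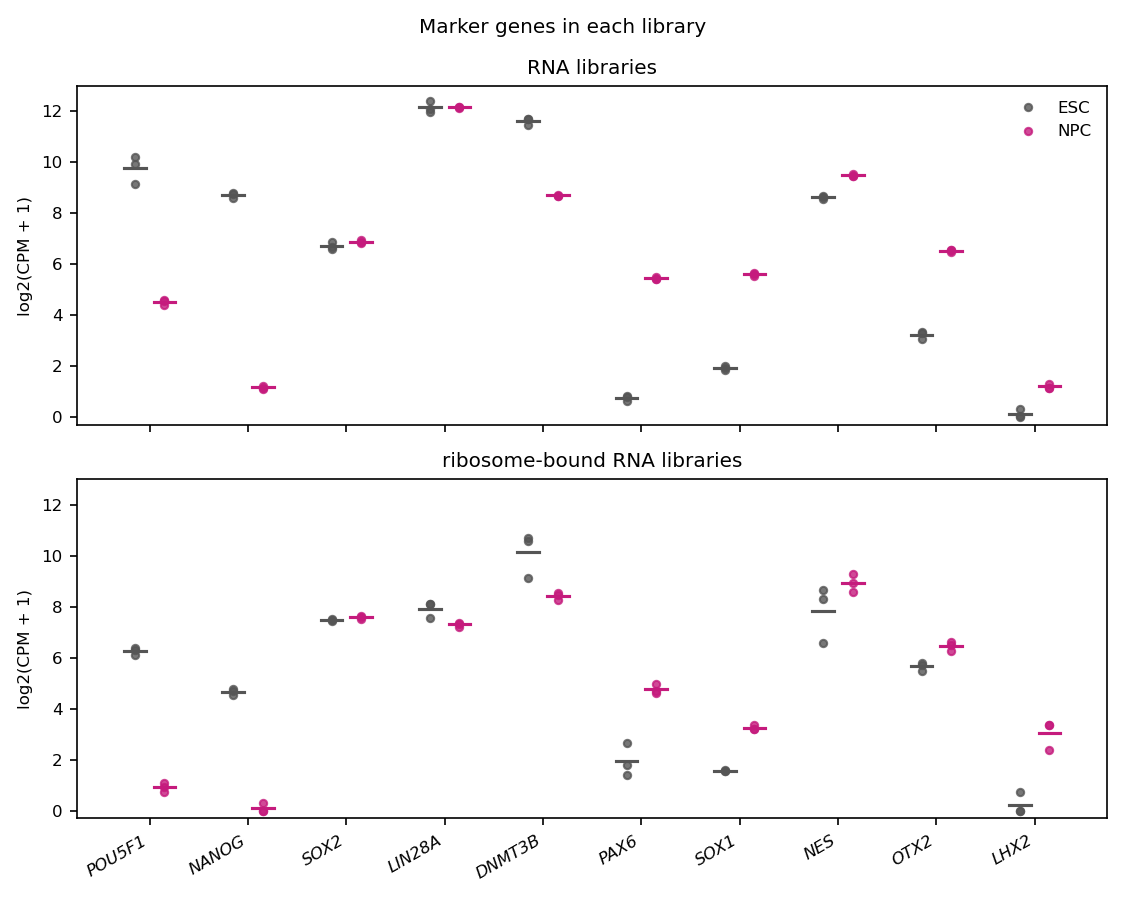
Expression of the 10 marker genes fixed beforehand, as log2(CPM + 1), in the RNA libraries (upper panel) and the ribosome-bound libraries (lower panel), with a point per library and a bar at the mean of the 3 ESC (grey) or NPC (pink) libraries. POU5F1 and NANOG were lower and PAX6, SOX1 and OTX2 higher in all NPC libraries of both assays, while SOX2 lay near the same level in both states.

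Of 18631 genes tested, 4913 were higher and 4878 lower in NPC RNA, and 2679 and 2677 of them differed by at least 2-fold. The largest rises past the threshold included PAX3 and TFAP2B, transcription factors of the dorsal neural tube and neural crest, which rose 513-fold (adjusted p = 2.63e-07) and 447-fold (adjusted p = 2.48e-07). DMRT3, a transcription factor of the dorsal telencephalon and spinal cord, rose by 7.95 ± 0.26 on the log2 scale (SE). GREM1, a secreted BMP antagonist, rose by 7.35 ± 0.23 (1.55 to 252 CPM), and DACH1, a transcriptional cofactor of the eye and forebrain, by 7.19 ± 0.22. The largest falls included GDF3, a ligand of the TGF-beta family (−9.22 ± 0.25, adjusted p = 2.40e-07), HHLA1 (−9.43 ± 0.23), TDGF1, the Nodal co-receptor (−8.07 ± 0.20), and NODAL itself (−7.63 ± 0.26). CYP2B6, a cytochrome P450 of drug metabolism, had 0 counts in all NPC libraries and was at least 585-fold lower. DNMT3B, the de novo DNA methyltransferase, fell from 3253 to 407 CPM (−3.00 ± 0.10, adjusted p = 5.53e-07). NES, an intermediate filament protein of neural stem cells, rose by 0.80 ± 0.09 (adjusted p = 1.80e-04). LHX2, a forebrain factor near the floor in ESC, rose by 3.71 ± 0.60 (adjusted p = 0.00124), or by 5.57 without RNA_ESC replicate 1.

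Next, the gene lists were examined. Among 20 pluripotency genes 16 fell and 1, SALL4, rose, with 17 past the threshold when adjusted over the list alone (camera, adjusted p = 7.76e-27; 0.00762 with an estimated correlation). Out of 30 neural progenitor and forebrain genes 25 rose and 1, LMO3, fell (27 adjusted over the list alone, adjusted p = 2.22e-23; 0.0141 with an estimated correlation). Neural crest and placode genes moved the same way, 11 of 14 rising and 3, among them ETS1 (−2.41 ± 0.18), falling (14 adjusted over the list alone, adjusted p = 1.78e-10; 0.0188 with an estimated correlation). Other fates gave mixed counts without a call by camera, while fry, which does not set a list against other genes, called neurons (adjusted p = 0.00369), trophoblast and amnion (adjusted p = 1.71e-04) and mesoderm and endoderm (adjusted p = 4.57e-04). In neurons 5 of 13 markers rose and 6 fell (11 adjusted over the list alone, adjusted p = 0.375), with the dendritic protein MAP2 up by 5.56 ± 0.14 and the migration protein DCX at −1.48 ± 0.17. Midbrain, hindbrain and spinal cord genes split 4 to 4 of 9 (8 adjusted over the list alone, adjusted p = 0.810), trophoblast and amnion genes 5 to 2 of 8 (7, adjusted p = 0.201), and mesenchymal and matrix genes 6 to 5 of 19 (12, adjusted p = 0.889).

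Genes tied to the signals that the inhibitors act on were examined next. Of 15 Nodal and TGF-beta targets 12 fell and 3 rose (15 adjusted over the list alone, adjusted p = 4.52e-14; 0.0144 with an estimated correlation). This list shares GDF3 and TDGF1 with the pluripotency list, CER1 with mesoderm and endoderm and TGFBI with the matrix list. BMP targets went up as a list, with 10 of 17 rising and 3 falling (13 adjusted over the list alone, adjusted p = 1.73e-05; 0.0362 with an estimated correlation). The list shares TFAP2A and DLX5 with neural crest, GATA2 and GATA3 with trophoblast and SMAD7 and BAMBI with Nodal targets. The rise included the antagonist GREM1, whereas ID1, an immediate target of BMP receptors, fell by 1.69 ± 0.32 (log2) and SMAD7, a feedback inhibitor, by 2.81 ± 0.13. Mesoderm and endoderm genes fell in 6 of 12 cases and rose in 2 (9 adjusted over the list alone, adjusted p = 0.0871). MIXL1, a factor of the primitive streak, fell by 5.79 ± 0.32. The list passed without RNA_ESC replicate 1 (adjusted p = 0.0447) and without RNA_NPC replicate 1, 2 or 3 (0.0436, 0.0319 and 0.0347). Notch genes rose in 11 of 18 cases and fell in 4 (15 adjusted over the list alone, adjusted p = 0.00334; 0.396 with an estimated correlation), led by the effector HES4 (5.71 ± 0.27). WNT genes rose in 10 of 20 cases and fell in 5 (15 adjusted over the list alone, adjusted p = 0.00124; adjusted p = 0.0704 with an estimated correlation), with WLS, the carrier that exports WNT proteins, going from 8.87 to 624 CPM. Of 16 epithelial genes 10 fell, such as the adhesion protein CDH1 (−1.69 ± 0.09), and 3 rose (13 adjusted over the list alone, adjusted p = 0.0230; adjusted p = 0.240 with an estimated correlation).

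Metabolic and housekeeping lists followed. Cholesterol synthesis fell in 20 of 21 members (20 adjusted over the list alone, adjusted p = 2.15e-10; 0.0144 with an estimated correlation), with a median log2 fold change of −1.41. All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone, median −1.77, adjusted p = 1.52e-08; adjusted p = 0.215 with an estimated correlation). Mitochondrial ribosomal proteins fell in 32 of 77 cases and rose in 0 (30 adjusted over the list alone, adjusted p = 0.0311; adjusted p = 0.476 with an estimated correlation), a call that ended without RNA_ESC replicate 2 (adjusted p = 0.0601). Initiation factors fell in 17 of 32 cases and rose in 0 (17 adjusted over the list alone, adjusted p = 0.0217; adjusted p = 0.138 with an estimated correlation). Cytosolic ribosomal proteins rose in 33 of 78 cases and fell in 4 (36 adjusted over the list alone, adjusted p = 0.0311; adjusted p = 0.839 with an estimated correlation). Glycolysis genes rose in 9 of 20 cases, such as the glucose carrier SLC2A1 (2.30 ± 0.19), and fell in 2 (11 adjusted over the list alone, adjusted p = 0.0217; adjusted p = 0.476 with an estimated correlation). Replication-dependent histones fell in 22 of 61 cases and rose in 1, HIST1H1T, whose call ended with the replicate number as a block (adjusted p = 0.0520). The list was called (18 adjusted over the list alone, median −0.60, adjusted p = 0.0369; adjusted p = 0.867 with an estimated correlation), but not without RNA_ESC replicate 1 (adjusted p = 0.0839) or 2 (0.129). In RNA_ESC replicate 3 the histone genes lay at a median log2 difference of −1.14 from the other ESC libraries. The medians were −0.44 for Notch and for glycolysis genes, −0.41 for epithelial genes, −0.40 for cytosolic ribosomal protein genes and −0.38 for oxidative phosphorylation genes.

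For the remaining RNA lists camera gave no call, while fry called cell cycle genes (adjusted p = 3.70e-06), chaperones (adjusted p = 0.00507) and chromatin regulators (adjusted p = 0.0190) as lower. Oxidative phosphorylation genes fell in 29 of 77 cases and rose in 4 (32 adjusted over the list alone, adjusted p = 0.137). Chaperones of protein folding fell in 15 of 27 and rose in 0 (17 adjusted over the list alone, adjusted p = 0.0857). Both lists passed without RNA_ESC replicate 3 (adjusted p = 0.00558 and 0.0476). Cell cycle genes fell in 16 of 31 cases and rose in 7 (23 adjusted over the list alone, adjusted p = 0.230), the latter including the CDK inhibitor CDKN1A (1.93 ± 0.18). RNA-binding and splicing regulators rose in 4 and fell in 10 of 29 cases (14 adjusted over the list alone, adjusted p = 0.565). Chromatin regulators rose in 6 and fell in 9 of 31 cases (15 adjusted over the list alone, adjusted p = 0.755), with the H3K27 demethylase KDM6B at 3.33 ± 0.26 and the SWI/SNF ATPase SMARCA2 at −4.73 ± 0.27. ATF4 targets of the integrated stress response rose in 5 and fell in 6 of 20 cases (11 adjusted over the list alone, adjusted p = 0.889). The m6A factors rose in 2 and fell in 2 of 16 cases (3, adjusted p = 0.810), and terminal oligopyrimidine mRNAs other than ribosomal proteins rose in 3 and fell in 3 of 18 cases (5, adjusted p = 0.679).

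The second comparison repeated the question for RNA bound to ribosomes. POU5F1 and NANOG fell and PAX6, SOX1 and OTX2 rose, as in RNA. In addition, all tested members of the histone list, which holds some pseudogenes such as HIST1H2APS4, were lower on ribosomes of NPC. Most nuclear mRNAs of the mitochondrial machinery were lower there as well. POU5F1 went from 75.8 ± 10.6 CPM in ESC to 0.925 ± 0.223 CPM in NPC (SD, n = 3), 80.2-fold lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.80e-07). NANOG had 225 counts in ESC and 1 in NPC, a ratio of 278 with a 95% counting interval of 49.4 to 11025. PAX6 rose from 3.10 ± 1.83 to 27.0 ± 3.63 CPM (log2 3.06 ± 0.35, adjusted p = 2.05e-05; 3.71 without RIBO_ESC replicate 3), SOX1 from 1.98 ± 0.162 to 8.73 ± 0.601 CPM and OTX2 from 50.0 ± 3.38 to 89.5 ± 9.52 CPM. Of 12250 genes tested, 3865 were higher and 3707 lower in NPC, and 3019 and 2617 of them differed by at least 2-fold.

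Among the largest changes past the threshold, DACH1 rose by 6.78 ± 0.35 on the log2 scale (adjusted p = 1.80e-07; 7.52 without RIBO_ESC replicate 1). MSX1, a homeobox gene of the dorsal neural tube and a BMP target, had 0 counts in ESC and was at least 34.2-fold higher in NPC. GDF3 fell from 566 to 1.70 CPM (−8.33 ± 0.43, adjusted p = 1.80e-07), TIMP4, an inhibitor of matrix proteases, by 7.83 ± 0.53, and MIXL1 by 7.52 ± 0.35. KLHL4 had 0 counts in NPC and was at least 99.3-fold lower. MAP2 rose by 5.95 ± 0.30 and WLS by 4.54 ± 0.26. DNMT3B fell by 1.82 ± 0.34 (adjusted p = 6.59e-04). SOX2 did not pass (0.15 ± 0.18, adjusted p = 0.481), nor did NES (0.92 ± 0.39, adjusted p = 0.0596). NES passed at 0.52 without RIBO_ESC replicate 2 (adjusted p = 0.00457) and at 1.30 without RIBO_ESC replicate 1 (adjusted p = 0.0140).

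All 54 tested members of the list of replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, fell on ribosomes (54 adjusted over the list alone, median −3.49, camera adjusted p = 7.81e-46; 0.0492 with an estimated correlation). HIST1H2AB fell from 292 ± 48.0 to 7.30 ± 2.28 CPM and HIST1H3J from 887 ± 245 to 33.1 ± 2.64 CPM. Mitochondrial ribosomal proteins fell in 73 of 74 cases (73 adjusted over the list alone, median −1.31, adjusted p = 8.85e-14; adjusted p = 0.121 with an estimated correlation). Oxidative phosphorylation genes fell in 57 of 72 cases and rose in 4 (62 adjusted over the list alone, median −1.37, adjusted p = 2.65e-10; adjusted p = 0.321 with an estimated correlation). NDUFA8, a subunit of complex I, went from 504 ± 14.5 to 69.5 ± 4.70 CPM. Cytosolic ribosomal proteins fell in 38 of 72 cases and rose in 14 (54 adjusted over the list alone, median −0.64, adjusted p = 0.00932; adjusted p = 0.775 with an estimated correlation). RPL3 went against the list, rising from 547 ± 45.7 to 2867 ± 226 CPM. Mitochondrially encoded mRNAs, which fell in RNA, gave 2 rises, 0 falls and 11 members not past the threshold (1 adjusted over the list alone, adjusted p = 0.555). Chromatin regulators rose in 24 of 31 cases and fell in 1, SMARCA2 (25 adjusted over the list alone, median 1.43, adjusted p = 2.28e-05; adjusted p = 0.341 with an estimated correlation). KDM6B rose by 3.45 ± 0.22. In RIBO_ESC replicate 2 chromatin regulators lay at a median log2 difference of −0.63 from the other ESC libraries, mitochondrially encoded mRNAs at 0.71, histones at 0.39, oxidative phosphorylation genes at 0.37 and cytosolic ribosomal proteins at 0.33. Matrix genes lay there at 0.56, m6A factors at −1.06, glycolysis genes at −0.58 and cell cycle genes at −0.53.

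Fate and signalling lists were then examined on ribosomes. Pluripotency genes fell in 16 of 20 cases and rose in 2 (18 adjusted over the list alone, adjusted p = 7.54e-12; 0.0411 with an estimated correlation). Neural progenitor genes rose in 21 of 26 cases and fell in 1 (24 adjusted over the list alone, adjusted p = 2.16e-09; 0.0421 with an estimated correlation). Neural crest and placode genes rose in 10 of 13 cases and fell in 2 (12 adjusted over the list alone, adjusted p = 9.22e-06; 0.0422 with an estimated correlation). Mesoderm and endoderm genes fell in 8 of 11 cases and rose in 0 (8 adjusted over the list alone, adjusted p = 5.22e-07; 0.0421 with an estimated correlation). Nodal targets fell in 12 of 15 cases and rose in 3 (15 adjusted over the list alone, adjusted p = 8.94e-08; adjusted p = 0.312 with an estimated correlation). In RIBO_ESC replicate 2 they lay at a median of 0.70 from the other ESC libraries. Cholesterol synthesis fell in 20 of 21 cases (21 adjusted over the list alone, median −2.22, adjusted p = 8.85e-14; 0.0411 with an estimated correlation). Lists with weaker calls were Notch, with 10 up and 5 down of 18 (17 adjusted over the list alone, adjusted p = 0.0264; adjusted p = 0.606 with an estimated correlation), and chaperones. Of the latter 14 of 27 fell and 1, HSP90AA1, rose (15 adjusted over the list alone, adjusted p = 0.0264; adjusted p = 0.397 with an estimated correlation). In RIBO_ESC replicate 2 Notch genes lay at 0.50 and chaperones at −0.57. BMP targets (8 up and 3 down of 14, 11 adjusted over the list alone, adjusted p = 0.0392; adjusted p = 0.581 with an estimated correlation) lost the call without RIBO_ESC replicate 1 (adjusted p = 0.0627) or 2 (0.111). Epithelial genes (3 up and 8 down of 15, 13 adjusted over the list alone, adjusted p = 0.0392; adjusted p = 0.238 with an estimated correlation) lost it without RIBO_NPC replicate 2 (0.0701) or 3 (0.0555). The lists of neurons, trophoblast, matrix, WNT, initiation factors, other terminal oligopyrimidine mRNAs, ATF4 targets, glycolysis, m6A factors and RNA-binding regulators had no call by camera. Of these, fry called neurons (adjusted p = 0.0122), WNT (adjusted p = 0.0284) and initiation factors (adjusted p = 0.0431). Cell cycle genes, 5 of 30 up and 14 down, passed when RIBO_ESC replicate 2 was left out (adjusted p = 0.0275, against 0.252 with it).

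**Figure D2:**
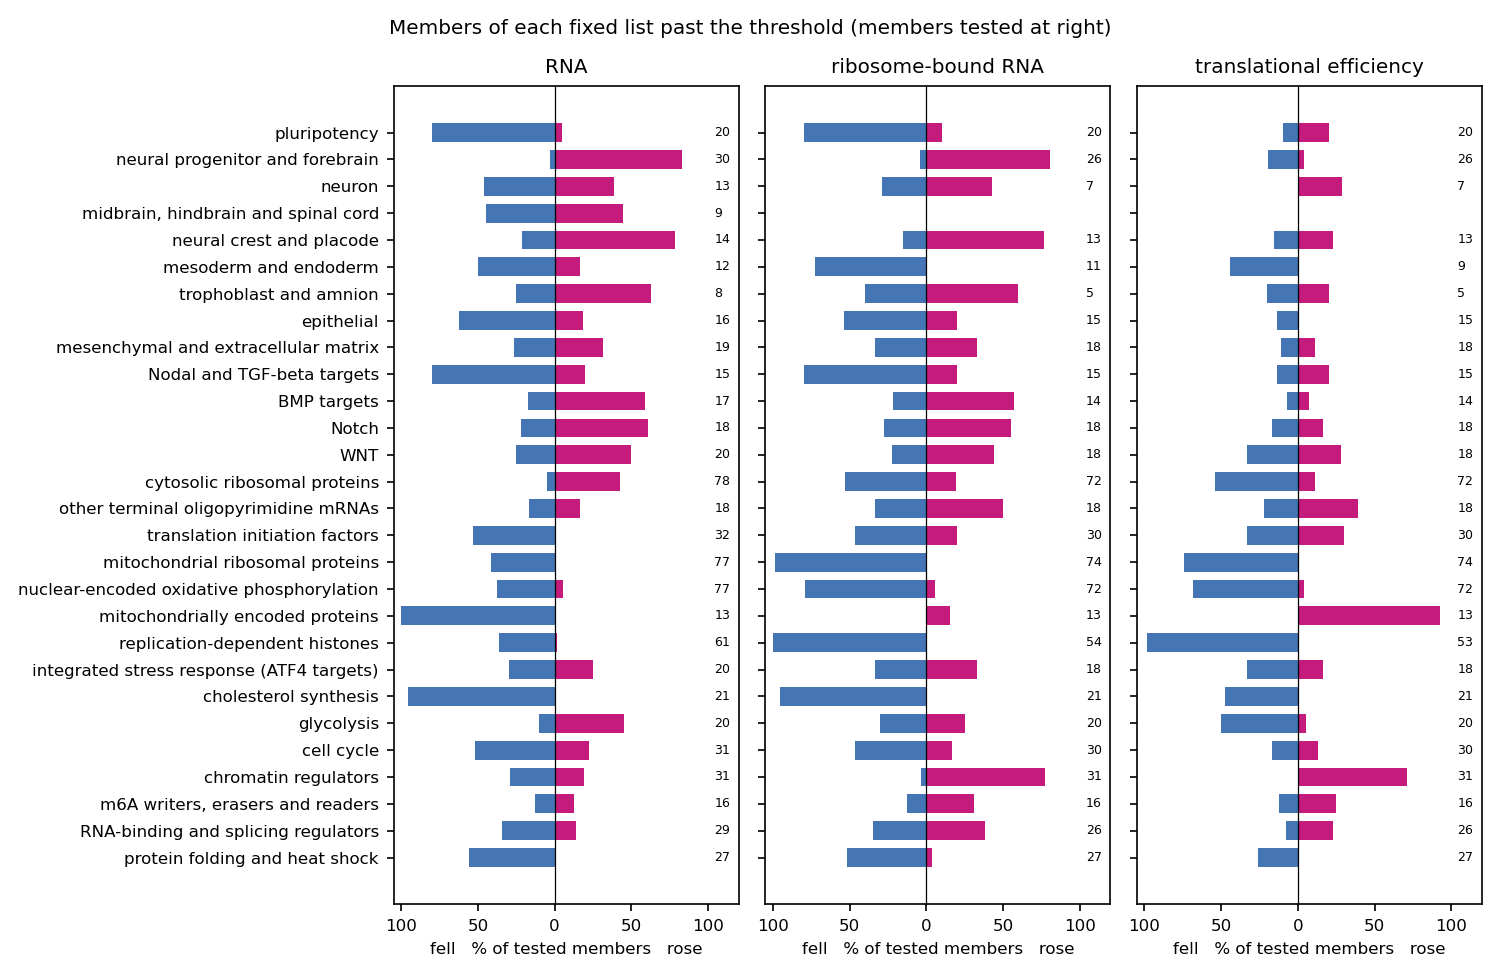
Percent of the tested members of each fixed gene list that rose (pink, to the right) or fell (blue, to the left) in NPC against ESC past the threshold, for RNA, ribosome-bound RNA and translational efficiency, with the number of members tested at the right of each panel. Histones, mitochondrial ribosomal proteins and oxidative phosphorylation genes fell in larger shares in ribosome-bound RNA than in RNA, with 54 of 54 histones falling on ribosomes and 22 of 61 in RNA.

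The third comparison asked how far changes on ribosomes followed those in RNA. Over the 11866 genes tested in both assays the log2 fold changes correlated at Pearson r = 0.725 and Spearman rho = 0.598, across genes, which are not independent replicates. Ribosome-bound changes were wider, with an SD over genes of 1.64 against 1.26 in RNA. Of 4291 genes called in both assays 1803 rose in both and 1974 fell in both, where independent lists of the same sizes would share 914 and 1028. GDF3, POU5F1 and MIXL1 were among those that fell in both, and DACH1, MAP2, WLS and PAX6 among those that rose. The other 514 genes moved in opposite directions, where independent lists would give 1946. Of the 514, 390 were lower in RNA and higher on ribosomes, and in 50 both changes reached 2-fold. Without both libraries that stood apart, RNA_ESC replicate 3 and RIBO_ESC replicate 2, 1210 genes moved in opposite directions.

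**Figure D3:**
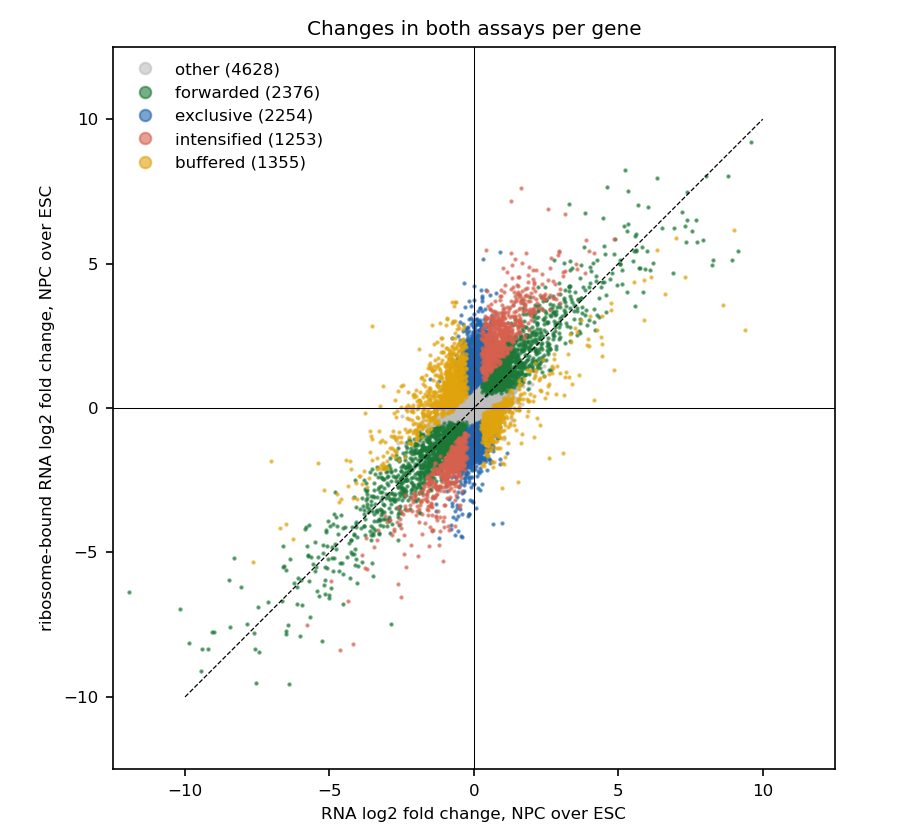
Log2 fold change of NPC over ESC in ribosome-bound RNA (vertical axis) against that in RNA (horizontal axis) for 11866 genes, a point per gene, coloured by class, with the dashed line at equal change. Forwarded genes (2376) lie along the line, exclusive genes (2254) spread vertically around a small RNA change, and buffered genes (1355) lie between the line and the horizontal axis or across it.

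Genes were then classed by their calls. In 2376 genes, such as POU5F1, RNA and ribosome-bound RNA changed the same way with no call for efficiency. A further 2254 changed on ribosomes and in efficiency with no call in RNA, among them RPL3 and EIF4G3, a scaffold of the cap-binding complex. Efficiency moved with RNA in 1253 genes, such as HIST1H2AB, and against it in 1355, such as PAX6, SOX1, OTX2 and JARID2. Calls by chance in independent lists of RNA and efficiency would give 661 genes rising in both (665 observed), 638 falling in both (588), 549 rising in RNA and falling in efficiency (500) and 768 the reverse (855). In 3 simulations with no change in efficiency edgeR called 0 genes in either class after adjustment, and at the unadjusted p limit of the real calls (0.0209) it placed 35 to 53 genes with RNA and 86 to 98 against it. Because the same RNA libraries enter both tests, part of any excess may come from them. The counts depended on single libraries. Without RNA_ESC replicate 3 there were 1336 exclusive genes, 2245 moving with RNA and 2244 against it. Without RNA_NPC replicate 1, 2 or 3 the genes moving with RNA numbered 776, 755 and 804, with 899 against it when replicate 2 was left out.

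The last comparison concerned translational efficiency itself. In NPC most tested mRNAs of histones, of mitochondrial ribosomal proteins and of oxidative phosphorylation, and 39 of 72 of cytosolic ribosomal proteins with 8 in the other direction, lost ribosome-bound RNA relative to their total RNA. Most mitochondrially encoded mRNAs and chromatin regulators gained it. None of these lists kept its camera call with an estimated correlation, the adjusted p then being 0.108, 0.108, 0.27, 0.471, 0.375 and 0.143 in this order. In the same ribosome-bound libraries RNU1-67P, a copy of the U1 spliceosomal RNA, took 0.0788% ± 0.0304 of counts in ESC and 2.06% ± 0.256 in NPC (SD, n = 3), and snoRNAs took 0.75% ± 0.283 and 1.39% ± 0.255. Of 11866 genes tested, 2716 had higher and 2254 lower efficiency in NPC, with 2265 and 1574 differing by at least 2-fold; without both libraries that stood apart the counts were 3634 and 3603. Within a state, log2 efficiency had an SD over genes of 1.504 in ESC and 1.37 in NPC. The ranks of genes correlated between states at Spearman rho = 0.664. PAX6, SOX1 and OTX2, whose RNA had risen, had lower efficiency in NPC, at −2.85 ± 0.44 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.23e-04; −2.19 without RIBO_ESC replicate 3), −1.89 ± 0.36 (adjusted p = 6.93e-04) and −2.59 ± 0.22 (adjusted p = 1.07e-06). Over all ESC libraries PAX6 had 46 RNA and 30 ribosome-bound counts and SOX1 189 and 18, so their ESC ratios rest on few counts. OTX2 already stood at 50.0 CPM on ESC ribosomes while its RNA stood at 8.70 CPM. POU5F1 (−0.98 ± 0.52, adjusted p = 0.136), SOX2 (−0.00 ± 0.20, adjusted p = 0.996) and NES (0.07 ± 0.45, adjusted p = 0.915) did not pass.

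Histones had lower efficiency in 52 of 53 cases (53 adjusted over the list alone, camera adjusted p = 4.49e-42; adjusted p = 0.108 with an estimated correlation), their median log2 efficiency going from 1.32 in ESC to −1.31 in NPC. Of genes with at least 5 CPM in each of the 4 groups, the 10 largest falls past the threshold were all histone genes, among them HIST1H2AB (−4.29 ± 0.39, adjusted p = 1.70e-06) and HIST1H4B (−4.11 ± 0.34, adjusted p = 9.97e-07), though reads may be split between near-identical copies. Mitochondrial ribosomal proteins fell in 55 of 74 cases (57 adjusted over the list alone, median −0.94, adjusted p = 1.01e-12; adjusted p = 0.108 with an estimated correlation). Oxidative phosphorylation genes fell in 49 of 72 cases and rose in 3 (55 adjusted over the list alone, median −1.10, adjusted p = 4.79e-11; adjusted p = 0.27 with an estimated correlation). Cytosolic ribosomal proteins fell in 39 of 72 cases and rose in 8 (50 adjusted over the list alone, median −1.02, adjusted p = 4.08e-09; adjusted p = 0.471 with an estimated correlation). NDUFA8 fell by 2.48 ± 0.20 (log2) and RPS2 by 2.99 ± 0.33, while RPL3 rose by 2.10 ± 0.25. In the other direction 12 of 13 mitochondrially encoded mRNAs rose (12 adjusted over the list alone, median 1.97, adjusted p = 5.22e-08; adjusted p = 0.375 with an estimated correlation), from a median log2 efficiency of −1.85 in ESC to 0.53 in NPC, led by MT-ND2 (2.74 ± 0.26) and MT-ND1 (2.56 ± 0.33) of complex I. Chromatin regulators rose in 22 of 31 cases and fell in 0 (22 adjusted over the list alone, median 1.49, adjusted p = 3.12e-09; adjusted p = 0.143 with an estimated correlation), with JARID2, a cofactor of Polycomb repressive complexes, at 2.53 ± 0.32.

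**Figure D4:**
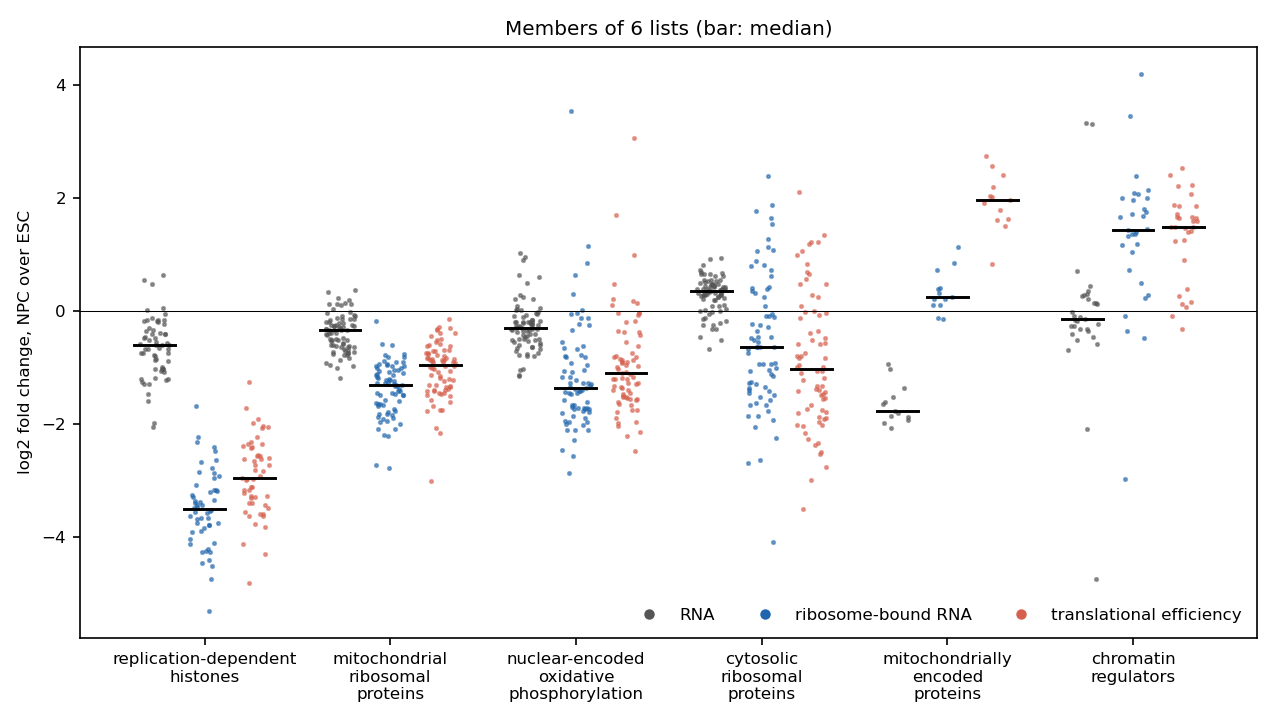
Log2 fold change of NPC over ESC for each member of 6 gene lists, in RNA (grey), ribosome-bound RNA (blue) and translational efficiency (red), with a point per gene and a black bar at the list median. Histone medians go from −0.60 in RNA to −3.49 on ribosomes, mitochondrially encoded mRNAs from −1.77 to 0.26, and chromatin regulators reach 1.49 in efficiency.

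Several other mRNAs gained efficiency in NPC. BDP1, a subunit of the RNA polymerase III factor TFIIIB, rose by 4.39 ± 0.36 (adjusted p = 9.97e-07), GOLGA4, a golgin of the trans-Golgi, by 4.25 ± 0.31, HIPK2, a nuclear kinase, by 3.68 ± 0.25 (adjusted p = 5.26e-07), and RB1CC1, which starts autophagosome formation, by 3.28 ± 0.32. Among initiation factors 9 of 30 rose, led by EIF4G3 (2.59 ± 0.27), and 10 fell, with no call for the list by camera or fry. Cholesterol synthesis fell in 10 of 21 cases and rose in 0 (10 adjusted over the list alone, median −0.86, adjusted p = 2.35e-04; adjusted p = 0.0972 with an estimated correlation). Glycolysis genes fell in 10 of 20 cases and rose in 1, the hexokinase HK1 (12 adjusted over the list alone, median −0.77, adjusted p = 0.00151; adjusted p = 0.471 with an estimated correlation). Mesoderm and endoderm genes fell in 4 of 9 cases and rose in 0 (5 adjusted over the list alone, adjusted p = 0.00975; adjusted p = 0.108 with an estimated correlation), led by GATA6, a factor of primitive endoderm (−5.07 ± 0.61). This call ended without RNA_ESC replicate 3 (adjusted p = 0.0502) and without both libraries that stood apart (0.201). The median log2 efficiency of this list in ESC was 3.49, against −0.37 over all genes tested. Whether both assays used the same cultures is not known here. A difference in cell make-up between cultures therefore cannot be told apart from a change in efficiency. Chaperones fell in 7 of 27 cases (2 adjusted over the list alone) without a call by camera or by fry (adjusted p = 0.192 and 0.0910). A camera call came without RIBO_ESC replicate 2 (adjusted p = 0.0204) or without both libraries (0.00651). The 20 pluripotency genes gave 4 rises and 2 falls and the 26 neural progenitor genes 1 rise and 5 falls (adjusted p = 0.190), and camera called neither list, while fry called the latter as lower (adjusted p = 0.0137). Of other lists without a camera call, fry called neurons as higher (adjusted p = 0.00156) and epithelial genes as lower (adjusted p = 0.0430). All 9 lists called for efficiency lost their call with an estimated correlation.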

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

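In this part the tests without both libraries that stood apart, that of mitochondrial rRNA and that of endoplasmic reticulum-bound mRNA were chosen only after the result was seen. The tests of gene span, depth and NPC material were set after the patterns they address were seen, but before their own results.

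For 6 of the genes named by the rule, RNA and ribosome-bound RNA changed in opposite directions, each past its threshold and by at least 2-fold, and the difference between the changes passed its own test, the interaction of assay and cell state (edgeR). SP5, a transcription factor induced by WNT, rose in RNA by 3.08 on the log2 scale and went by −1.57 on ribosomes, an efficiency change of −4.70 (SE 0.49, adjusted p = 4.46e-06; −5.81 without RNA_ESC replicate 2). DKK1, a secreted WNT antagonist, stood at 1.52 in RNA and −2.56 on ribosomes, with an efficiency change of −4.13 (SE 0.58, adjusted p = 5.83e-05). SLC16A3, a lactate exporter, stood at 2.09 and −1.02, with an efficiency change of −3.17 (SE 0.45, adjusted p = 6.75e-05; −2.44 without both libraries that stood apart). The opposite order was seen for MT-ND2, a mitochondrially encoded subunit of complex I, with −1.65 in RNA, 1.14 on ribosomes and an efficiency change of 2.74 (SE 0.26, adjusted p = 2.15e-06). SRSF2, a splicing factor, stood at −1.15 and 2.42, with an efficiency change of 3.53 (SE 0.32, adjusted p = 1.70e-06). ZNF721, a zinc finger protein, stood at −1.29 and 2.29, with an efficiency change of 3.53 (SE 0.37, adjusted p = 4.59e-06).

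The efficiency of short-gene groups, namely histones, both kinds of ribosomal proteins and oxidative phosphorylation genes, fell in NPC, while that of chromatin regulators, with a median span of 90.3 kb, rose. Over 11368 protein-coding genes, which are not independent replicates, the efficiency change correlated with gene span at Spearman rho = 0.37, against −0.04 for RNA and 0.249 for ribosome-bound RNA. Without both libraries that stood apart the value for efficiency was 0.274, so part of the span trend came with these libraries. With the span trend of genes outside the lists removed, the histone median was −1.98 (SE 0.13, from −2.95). That of ribosomal protein and oxidative phosphorylation genes together was −0.81 (SE 0.08, from −1.001) and that of chromatin regulators 1.10 (SE 0.15, from 1.49). For the ribosomal protein and oxidative phosphorylation genes and for chromatin regulators the fitted trend thus took up only part of the median. For histones the trend was poorly set, since their median span was 0.4935 kb, against 3.625 kb in the shortest decile of protein-coding genes. The histone value therefore does not decide how much of their fall goes with gene span. These SEs treat list members as independent, although the estimated correlation between histones was 0.59. They are therefore too small to decide whether gene span is the whole cause. Without both libraries that stood apart the median over the 4 falling lists was −1.03 (SE 0.09, from −1.27). That of chromatin regulators was 1.28 (SE 0.17, from 1.49), so neither pattern rested on these libraries alone. A difference between the states in the isolation of ribosome-bound RNA and a difference in translation itself were not tested and stay open. Effects of GC content and of the length of mRNAs or their coding sequences were not tested either and stay open. Gene span includes introns, so removing its trend does not remove a trend on mRNA length. Nuclear RNAs also differed in these libraries, with RNU1-67P at 0.0788% of ribosome-bound counts in ESC and 2.06% in NPC.

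Mitochondrially encoded mRNAs fell in RNA (median −1.77) and not in ribosome-bound RNA (median 0.26), a median efficiency change of 1.97. Without both libraries that stood apart it was 2.22 (SE 0.16, over genes), so the pattern did not rest on these libraries alone. If more mitochondrial ribosomes had been recovered from NPC, their rRNA should have moved with the mRNAs, and the ribosome-bound changes of MT-RNR2, −0.51 (SE 0.43), and MT-RNR1, 0.36 (SE 0.33), lay below and above the 0.26 of the mRNAs, each by less than 2 standard errors. Since rRNA was depleted from the RNA libraries, the abundance of mitochondrial ribosomes is unknown, and their recovery and a change in translation cannot be told apart.

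RNA_ESC replicate 3 and RIBO_ESC replicate 2 stood apart from the other replicates. Lower depth is argued against by the other libraries thinned to their depth, which still correlated at Pearson r = 0.9965 in RNA and 0.978 in ribosome-bound RNA across genes, where the libraries in question reached at most 0.954 and 0.940. NPC material is argued against by NPC-specific genes. These lay above the other ESC libraries by a median of 0.0892% of their NPC level in RNA_ESC replicate 3 (29 genes, upper quartile 0.625%). In RIBO_ESC replicate 2 the median was −0.779% (27 genes, upper quartile 0%). Over protein-coding genes alone, the deviation of RNA_ESC replicate 3 correlated with gene span at Spearman rho = 0.41. With the span trend removed, its Pearson r with replicate 1 over these genes went from 0.947 to 0.956. This argues against gene span as the whole cause for RNA_ESC replicate 3, and span was not tested for RIBO_ESC replicate 2. In RIBO_ESC replicate 2 the median deviation of matrix genes exceeded that of initiation factors by 0.949, but histones (0.39), cytosolic ribosomal proteins (0.33) and mitochondrially encoded mRNAs (0.71), not made at the endoplasmic reticulum, were high as well, so whether its share of endoplasmic reticulum-bound mRNA was larger stays open. Differences in culture or isolation stay open, and no biological explanation was tested, since the design names none.

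Genes past the threshold were also counted for the 10 splits of the libraries into 3 against 3, taking pairs of same-numbered RNA and ribosome-bound libraries for efficiency. Deviations from the group means correlated within these pairs at −0.139, 0.16 and 0.098 in ESC and −0.043, −0.025 and −0.195 in NPC. The values thus did not show that the numbers pair the 2 assays. In each comparison 1 split, the real one, reached the real count, and 10 splits are too few for a share under 0.05. With edgeR the real split called 9791 genes for RNA, 7572 for ribosome-bound RNA and 4970 for efficiency, and the highest other split 0 in each. Every other split placed both states on each side, so the difference between the states entered its spread and few calls were possible. The splits therefore do not decide what part chance had in the real counts. At an unadjusted p under 0.05 the real counts were 10840, 8044 and 5994 and the highest others 569, 274 and 114, and no other tool was run on the splits. For RNA, whose replicate numbers were taken to pair the libraries, the 3 other splits that part all 3 pairs reached 98 genes at the unadjusted p, and the 6 that part 1 pair reached 569.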

How the results depend on the processing

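Fits without both libraries that stood apart, list tests with the replicate block and the alternatives for efficiency levels were chosen after seeing the data. A minimum of 2-fold left 2679 genes higher and 2677 lower in RNA, and 1419 forwarded, 363 intensified (efficiency moving with RNA) and 430 buffered genes (against it), since fewer genes can pass. Without a filter on low counts the correlation of RNA and ribosome-bound fold changes was 0.501 (0.725 with it). Without both libraries that stood apart 3603 genes had lower efficiency, 2749 were intensified and 2767 buffered, and the cause was not tested. Leaving out each library in turn gave 1336 to 2434 exclusive genes (without RNA_ESC replicate 3 and RIBO_ESC replicate 2), 755 to 2245 intensified and 899 to 2244 buffered (without RNA_NPC replicate 2 and RNA_ESC replicate 3), and the cause was not tested. FEZF2 reversed. It had 0 counts in the RNA libraries of ESC and 4 in their ribosome-bound libraries, all in RIBO_ESC replicate 3, so its fitted efficiency change rests on these counts and is no bound. The fitted value, −4.16 with all libraries (adjusted p = 0.0394), was 1.78 without RIBO_ESC replicate 3 (adjusted p = 0.9998, the highest of its alternatives, the lowest being 0.0110 with DESeq2) and at its lowest −4.86 without RIBO_ESC replicate 1.

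With an estimated correlation in place of the preset, camera called 6 of 28 lists for RNA (15 before), 6 of 27 for ribosome-bound RNA (15 before) and 0 of 27 for efficiency (9 before). The cause was not tested. The 0 of camera compares with 5 lists at an unadjusted p under 0.05 and with 12 by fry, which does not set a list against other genes.

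Genes that moved in opposite directions in RNA and on ribosomes went from 514 to 1210 without both libraries. Outside the minimum of 2-fold, the counts of genes higher or lower in RNA and in ribosome-bound RNA stayed within 1.5 times their value. Without each library in turn, RNA gave 3804 to 6757 genes higher and 4030 to 6710 lower, ribosome-bound RNA 3533 to 4429 and 3123 to 4245, and efficiency 2355 to 3062 and 1735 to 2842. Forwarded genes numbered 2264 to 2632, the correlation of fold changes was 0.706 to 0.729, the rank correlation of efficiency between states 0.643 to 0.675, and lists called 13 to 17, 14 to 15 and 8 to 10. Of genes called for efficiency 54.6% were higher with TMM, 50.5% with RLE size factors and 49.3% with DESeq2. Direction and call held under every alternative for 97 of 121 named genes in RNA, 110 of 116 in ribosome-bound RNA and 93 of 112 for efficiency.

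With the replicate number as a block, edgeR called 5103 genes higher and 4973 lower in RNA. Of the calls of the main fit without a block, 4692 of 4913 rises and 4750 of 4878 falls stayed. Beyond HIST1H1T it ended the RNA calls of APOA1 and RBM15, and in RNA it changed no other call of a named gene and none of a list. In ribosome-bound RNA the same-numbered libraries deviated from their group means with correlations of −0.252, −0.332 and −0.021, and the numbers were not taken to pair them. In neither assay did every library correlate best with its own number. In ribosome-bound RNA the block gave 3574 higher and 3191 lower, and for efficiency 2537 and 2060, or 2593 and 2173 with a block for each state and number. Calls of named genes ended for 2 of 116 in ribosome-bound RNA and for 8 of 112 in efficiency, or 2 with a block for each state and number.

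Depth sets how little could be seen of a gene without counts. Such a gene could have been present at up to 0.0854 to 0.154 CPM in the RNA libraries and at up to 0.674 to 1.24 CPM in the ribosome-bound libraries.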

Other observations

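The gene families and noncoding RNAs in this part, and all tests of them, were chosen after values were seen.

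In several further protein families more members passed in one direction of efficiency than in the other. Over all 11866 genes tested, 2716 rose and 2254 fell. The efficiency change also followed gene span over protein-coding genes (Spearman rho = 0.37), and that trend was not removed for these families. The length of their mRNAs was not examined. Out of 14 families tested with camera under a preset correlation none kept a call for efficiency with an estimated correlation, and since families were chosen after values were seen the p-values are descriptive. Centrosomal proteins, which build centrioles and cilia, had higher efficiency in NPC in 18 of 32 cases and lower in 1, CEP68 (median log2 1.34, adjusted p = 2.69e-06; adjusted p = 0.289 with an estimated correlation), among them CEP290 (3.24 ± 0.41, SE) and CEP350 (2.36 ± 0.32). Kinesins, the motors of microtubules, rose in 17 of 32 cases and fell in 0 (median 1.03, adjusted p = 4.71e-06; adjusted p = 0.177 with an estimated correlation), with KIF5B at 1.79 ± 0.26. Myosins rose in 13 of 20 and fell in 0 (median 1.31, adjusted p = 1.29e-06; adjusted p = 0.155 with an estimated correlation). Zinc finger genes rose in 100 of 380 cases and fell in 25 (median 0.35, adjusted p = 0.0380; adjusted p = 0.604 with an estimated correlation). The share of zinc finger genes that rose was close to that over all genes. In the other direction, subunits of the proteasome fell in 17 of 30 cases and rose in 1, PSMD4 (median −0.71, adjusted p = 1.39e-04; adjusted p = 0.177 with an estimated correlation), with PSMA4 at −1.78 ± 0.25 and PSMB3 at −1.41 ± 0.25. Aminoacyl-tRNA synthetases fell in 14 of 32 and rose in 0 (median −0.64, adjusted p = 0.00413; adjusted p = 0.319 with an estimated correlation), and subunits of the vacuolar ATPase in 8 of 14, with 0 rising (median −0.84, adjusted p = 0.0141; adjusted p = 0.155 with an estimated correlation).

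Without both libraries that stood apart, the median efficiency changes were 1.24 for centrosomal proteins, 0.87 for kinesins, 1.30 for myosins, 0.19 for zinc finger genes, −0.83 for proteasome subunits, −0.75 for tRNA synthetases and −0.70 for the vacuolar ATPase. Falls then numbered 69 of 402 zinc finger genes (25 of 380 with all libraries), 5 of 33 kinesins (0 of 32) and 15 of 21 nucleoporins (4 of 21). In RNA the family with the strongest call was that of the protocadherins, adhesion proteins of neural cells, of which 37 of 67 rose and 9 fell (median 0.59, adjusted p = 4.75e-04; adjusted p = 0.354 with an estimated correlation). With all libraries camera gave no call for efficiency in 7 families: nucleoporins, protocadherins, Sm and LSm proteins, ubiquitin-specific proteases, mediator subunits, RNA polymerase II subunits and the SLC7 carriers.

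Noncoding RNAs also differed between the states. Y RNAs, small RNAs transcribed by RNA polymerase III, went from 0.329% ± 0.0535 of the ribosome-bound counts in ESC to 2.08% ± 0.468 in NPC (SD, n = 3), and among them RNY1 rose from 3289 to 21239 CPM (log2 2.69 ± 0.34, edgeR adjusted p = 3.77e-05). RNU1-67P, a copy of the U1 spliceosomal RNA, went from 0.0788% ± 0.0304 to 2.06% ± 0.256 and snoRNAs from 0.75% ± 0.283 to 1.39% ± 0.255. NEAT1, a nuclear lncRNA, rose by 3.16 ± 0.10 in RNA (adjusted p = 4.27e-07) and had 1 ribosome-bound count in ESC and 168 in NPC, a ratio of 136 with a 95% counting interval of 24.1 to 5404. MALAT1, another nuclear lncRNA, rose by 2.36 ± 0.16 in RNA (adjusted p = 1.21e-05) and by 3.82 ± 0.27 in ribosome-bound RNA (230.5 to 3245 CPM, adjusted p = 8.19e-07). ESRG, a lncRNA of pluripotent cells, fell by 4.75 ± 0.12 in RNA and by 4.07 ± 0.26 on ribosomes. The snoRNA host gene SNHG14 went by −1.01 ± 0.09 in RNA and 1.53 ± 0.20 in ribosome-bound RNA, with an efficiency change of 2.49 ± 0.26 (adjusted p = 4.70e-06), and SNHG1 by −0.66 ± 0.09 and 1.17 ± 0.38, with an efficiency change of 1.79 ± 0.42 (adjusted p = 0.00320). Whether such RNAs were bound by ribosomes or came down with them was not measured. SNHG1 stood at 2137 CPM in ESC and 4823 CPM in NPC in ribosome-bound RNA, against 329 and 208 CPM in RNA. Whether reads of snoRNAs were counted to their host genes is not known, so the efficiency changes of SNHG14 and SNHG1 are uncertain.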
